A study of Homo sapiens with 12 samples.

How the data were processed

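Total RNA from U2OS cells, a human osteosarcoma line, was hybridised to single-colour Agilent arrays with 60-base probes. The cells stably expressed either the wild-type glucocorticoid receptor (WT GR) or the S134A receptor, in which a serine that can be phosphorylated is replaced by alanine. Per the labels' protocols, each population was a mixed, antibiotic-selected culture that grew in hormone-depleted serum before treatment. Cells then received 100 nM dexamethasone, a synthetic glucocorticoid, or water as vehicle for 6 h. There were 12 arrays, 3 in each of 4 groups, on 3 slides of 4 arrays. Slide 1 held WT vehicle 1, WT Dex 2 and S134A vehicle 1 and 3. Slide 2 held WT vehicle 2, WT Dex 1 and S134A Dex 1 and 3. Slide 3 held the third vehicle and Dex arrays of WT cells with S134A vehicle 2 and Dex 2, and was the only slide with both treatments of both populations. The series design calls the replicates biological but also mentions a repeat hybridisation, and the labels mark no array as such a repeat. The p-values therefore measure the spread between these arrays, part of which may be technical. Each receptor was represented by a single selected population, so the p-values hold no spread between populations with the same receptor. Differences between S134A and WT cells may thus come from the receptor or from other differences between the populations.

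The deposited scanner files held an intensity per spot in Cy3. Per the submitters' processing notes they were made with Agilent Feature Extraction version 9.5. Per the file headers, the processed intensity was background-subtracted and detrended within the array, with surrogate values for dim spots, and was not normalized between arrays. The deposited mean and local background intensity of each spot were uncorrected, per the file headers. The deposited series matrix held the same processed intensity on all 12 arrays, with no further scaling or centring. No normalization between arrays by the authors is given in the sources used here.

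Processed intensities were log2-transformed, and each array's 75th percentile over the 43376 spots that were not controls was subtracted. Spots marked as outliers by the scanner software (53 to 110 per array) were left out, and spots of the same probe were averaged. Of 41000 probes, 31012 were kept because they were well above background on every array of at least 1 group. The brightest kept probe stood for its gene, which left 23164 genes, and 5962 of these had several kept probes. Probes were named through the RefSeq table of GRCh38.p14 by accession (23434 probes), symbol (2317) or older symbol (1043). The other 14206 probes kept the name of the array design. Of the tested genes, 14860 had a symbol in that table. Probe coordinates are those of hg17, as in the file headers, and the RefSeq table served only for names and for which genes are neighbours.

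Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with statmod 1.5.0 and version 1.17.8 of data.table). All 12 arrays entered a single fit of 4 group means with 8 residual degrees of freedom, a prior SD of 0.139 and a prior df of 2.75. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p under 0.05. The comparisons were dexamethasone against vehicle in WT cells and in S134A cells, the difference of these responses (S134A minus WT, tested as an interaction), and S134A minus WT under vehicle and under dexamethasone. Errors of log2 changes are standard errors from limma, with 3 arrays per group. For a gene whose probes were all not well above background in a group, the change is given as at least N-fold. This bound sets the bright group's mean against the dim group's mean of, on each array, the higher of the lowest signal well above background and the probe's own signal. Counts of genes changed at least 2-fold or 4-fold use limma's estimate instead, also for such genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

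The test and the covariates, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes each way among called genes with a symbol whose groups did not overlap (5 each way between populations under dexamethasone, and no overlap condition for the interaction). It also took the 4 members of each list with the smallest p, and 12 genes whatever they did: NR3C1, FKBP5, TSC22D3, PER1, DUSP1, SGK1, KLF9, ZBTB16, MT2A, IGFBP1, LAD1 and YWHAZ. Some genes that the rule took are not reported here. Other genes were chosen after their values were seen, and are said to be so where they appear.

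The 32 lists covered classical GR-induced genes, metallothioneins, inflammatory cytokines and effectors, AP-1 and immediate early genes, matrix metalloproteases and the plasminogen system, and the circadian clock. They also covered osteoblast differentiation, extracellular matrix and adhesion, cholesterol biosynthesis, glycolysis and gluconeogenesis, insulin and IGF signalling, adipogenic and lipid droplet genes, and the G2/M and G1/S phases of the cell cycle. Stress and signalling lists were p53 targets, interferon-stimulated genes, the unfolded protein response, heat shock proteins, GR chaperones and coregulators, the 14-3-3 family, MAPK phosphatases and feedback regulators, the p38 MAPK pathway, the Wnt pathway, TGF-beta and BMP targets and apoptosis regulators. The rest were epithelial sodium transport, ribosomal proteins, mitochondrial respiration, and markers of epithelial, haematopoietic, endothelial and liver cells. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Limma's fry, which asks whether a list's genes move on balance one way, was run as well.

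Scripts were tested on simulated data with the real means and spreads and known changes in a seeded set of genes. At 2-fold, 53 of 67 changed genes were recovered for dexamethasone in WT cells, 57 of 67 in S134A cells, 40 of 67 for the interaction, 56 of 67 between populations under vehicle and 57 of 67 under dexamethasone. At 1.5-fold the numbers of 67 were 35, 31, 7, 35 and 34, and at 4-fold, of 66, they were 63, 63, 61, 65 and 63. False calls among 22964 unchanged genes numbered 12, 7, 6, 11 and 12. The small number of arrays limits the precision. Simulated genes varied independently, without slide or brightness effects, and a far smaller share changed than was called in the real data. Recovery and false calls in the real data may therefore differ from these numbers.

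Alternatives covered background correction (normexp, offset 50), quantile and median scaling, no filter or a filter on all 12 arrays, the mean over a gene's probes, and the series matrix values. They also covered slide as a fixed or random block, the replicate number as a block, trend and robust variance, array weights, fits of only the groups compared, stricter thresholds, and each array left out in turn. An array's brightness as a covariate, slide 3 alone, the filter on all 12 arrays together with a 2-fold change, and a normexp fit on the negative control spots were added after seeing the data.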

Results

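Gene expression was profiled in U2OS osteosarcoma cells that carried either the WT glucocorticoid receptor or the S134A receptor, after 6 h of 100 nM dexamethasone (Dex) or vehicle, with 3 arrays in each of the 4 groups. The 75th percentile of the processed intensity ranged from 1445 to 2988 between arrays, and 72.9% to 80.8% of the spots on an array were well above background. Replicate arrays of a group correlated at r = 0.991 to 0.997 across genes, which are not independent replicates. The median SD between replicates was 0.112 to 0.171 on the log2 scale, and the median standard error of a log2 change was 0.121.

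NR3C1, the gene of the glucocorticoid receptor itself, was measured first because the transfected receptor sets the cell populations apart. Its level relative to the array's 75th percentile was 0.70 ± 0.09 (log2, SD, n = 3) in WT vehicle, 0.62 ± 0.01 in S134A vehicle, -0.20 ± 0.04 in WT Dex and -0.60 ± 0.16 in S134A Dex. Under vehicle the populations differed by -0.08 ± 0.09 (limma, adjusted p = 0.556, exact permutation p = 0.4), and a second probe gave 0.24 ± 0.09 (limma, adjusted p = 0.0796). With Dex, NR3C1 fell by 0.89 in WT cells and by 1.21 in S134A cells on the log2 scale (limma, adjusted p = 1.47e-05 and 6e-07). The exact permutation p of each of these falls was 0.1, the smallest that 3 arrays against 3 can give. The probe lies on chromosome 5 at 142641130 to 142641189 (hg17) and the second probe at 142639483 to 142639542. Stop codons occur in 1 of 3 frames of the former and in all 3 frames of the latter, so neither is known to detect the transfected coding sequence, and these values do not check the construct.

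**Figure D1:**
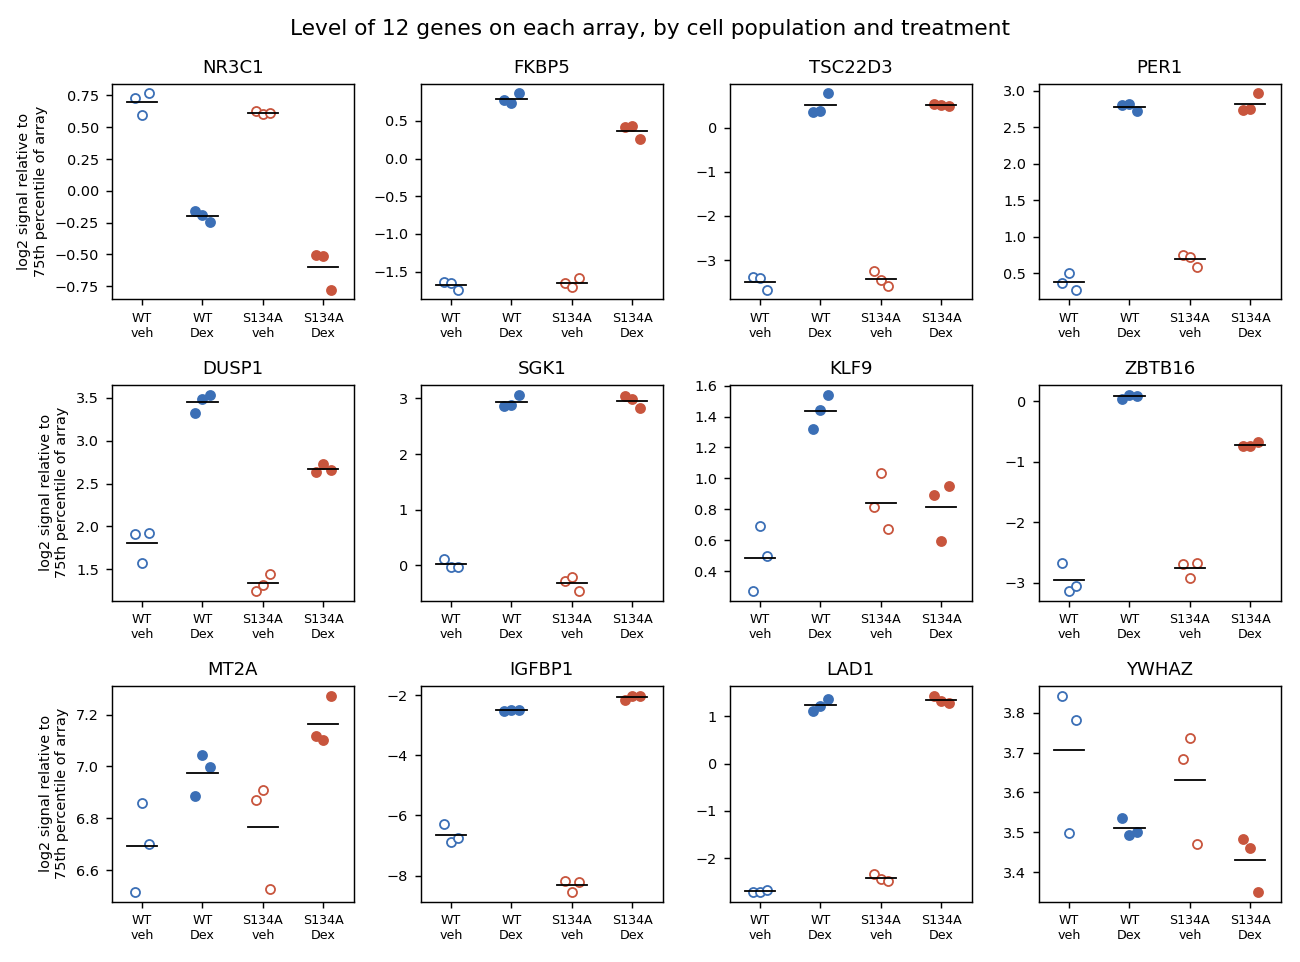
Level of the 12 genes reported whatever they did, on each of the 12 arrays (log2 signal relative to the array's 75th percentile). Points are arrays, black lines are group means, and open points are vehicle. IGFBP1 in S134A vehicle was not well above background.

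The first comparison asked which genes the hormone changes through the WT receptor. Dex strongly raised many genes that were dim or silent without hormone. KDF1, a factor of keratinocyte differentiation, rose at least 205-fold, SAG, the arrestin of the retina, at least 179-fold, SPINK13, a protease inhibitor, at least 219-fold, and CYTIP, a lymphocyte adaptor, at least 121-fold. ATP4A, a subunit of the gastric proton pump, rose at least 111-fold, the kidney cadherin CDH16 at least 87.7-fold and the cystatin-like CST9L at least 52-fold. FAM90A1, of a gene family with many near-identical copies that the probe may not separate, rose by 9.63 ± 0.11 on the log2 scale. TF, which encodes transferrin, rose by 8.18 ± 0.16 and the testis gene ACTL8 by 8.07 ± 0.13, where 2 and 1 of the 3 vehicle arrays measured them. The falls were smaller. DRD1, a dopamine receptor, fell by 3.80, with 1 of 3 Dex arrays above background, the growth factor CSF2 by 3.08 and TP63, a relative of p53, by 2.57 (2 of 3 Dex arrays each). The adhesion gene AMIGO2 fell by 3.15, TNFAIP6, a hyaluronan-binding protein of inflammation, by 2.92, the immediate early gene IER3 by 2.58 and the monocyte chemokine CCL2 by 2.58. The chemokine receptor CCR1 fell at least 4.38-fold, the scaffold gene GRIP2 at least 3.28-fold and SOSTDC1, a BMP antagonist, at least 1.87-fold.

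Well-known targets of the receptor rose in WT cells. TSC22D3, an anti-inflammatory leucine zipper protein, rose by 3.98 ± 0.13 (log2 ± SE, 3 arrays per group), LAD1, a basement membrane protein, by 3.94 ± 0.08, the transcription factor ZBTB16 by 3.04 ± 0.12 and the kinase SGK1 by 2.91 ± 0.10. FKBP5, an Hsp90 cochaperone that restrains the receptor, rose by 2.47 ± 0.08, the clock gene PER1 by 2.39 ± 0.09, the MAPK phosphatase DUSP1 by 1.64 ± 0.11 and the transcription factor KLF9 by 0.95 ± 0.14. IGFBP1, which binds insulin-like growth factors, rose by 4.14 ± 0.15, with 1 of 3 vehicle arrays above background. The metallothionein MT2A changed by 0.28 ± 0.12 (limma, adjusted p = 0.105) and the 14-3-3 gene YWHAZ by -0.20 ± 0.10 (0.188), neither past the threshold.

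Across the genome, 6651 of 23164 genes (28.7%) changed with Dex in WT cells in limma's test, 3381 higher and 3270 lower, and 610 rose but 43 fell at least 4-fold. The share of calls that were higher was 50.8% and fell to 37.9% when arrays were scaled to their medians, which moved the median change of all genes from -0.04 to -0.11. With slide as a block 6476 genes were called.

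Among the lists, the classical GR-induced genes rose together in WT cells: 15 of 19 rose and none fell, and 16 rose when adjusted over the list alone (camera, adjusted p = 1.44e-13, and 0.00665 with an estimated correlation). It was the only list call of this comparison that held with an estimated correlation. TIPARP, an ADP-ribosyltransferase, rose by 4.35 ± 0.10 and the transcription factor CEBPD by 3.92 ± 0.09, and the mean of the list was 2.12, 2.03 and 2.07 within slides 1, 2 and 3. Of 10 metallothioneins, 8 rose, among them MT1M by 1.29 ± 0.17 and MT1E by 0.96 ± 0.14, and 9 when adjusted over the list alone (camera, adjusted p = 0.000405, but adjusted p = 0.467 with an estimated correlation). Endothelial markers rose in 4 of 7 cases, also adjusted over the list alone, with VWF, the von Willebrand factor, higher by 1.64 ± 0.09 and KDR, a VEGF receptor, at least 8.84-fold (camera, adjusted p = 0.0141, adjusted p = 0.324 with an estimated correlation and 0.24 over genes above background on all 12 arrays).

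Several inflammatory and immediate early genes fell in WT cells. Of 17 inflammatory cytokines and effectors, 8 fell, including LIF by 2.25 and IL6 by 1.26, and 3 rose, with the same counts adjusted over the list alone (camera, adjusted p = 0.0229, adjusted p = 0.239 with an estimated correlation). The risers were NOS2, the inducible nitric oxide synthase, by 3.06 ± 0.10, TNFAIP3, which restrains NF-kappaB, and PTGS2, the prostaglandin-forming cyclooxygenase. This list's call ended without WT vehicle 1 (adjusted p = 0.0645) and over genes above background on all 12 arrays (adjusted p = 0.417). Of 18 AP-1 and immediate early genes, 9 fell, among them IER2 by 1.40 and FOSL1 by 1.36, and 10 when adjusted over the list alone (camera, adjusted p = 0.0141, adjusted p = 0.288 with an estimated correlation). FOS, a core AP-1 subunit, and the orphan nuclear receptor NR4A1 rose. Of 24 G2/M genes, 4 fell, with CDC25C, a mitotic phosphatase, lower by 0.46, and 1 when adjusted over the list alone (camera, adjusted p = 0.0492, adjusted p = 0.467 with an estimated correlation and 0.0553 with slide as a block). Leaving out S134A Dex 1, S134A vehicle 1 or 2, WT Dex 2 or 3 or WT vehicle 1 also ended this G2/M call, with adjusted p-values of 0.0509 to 0.125. So did quantile normalization (camera, adjusted p = 0.174) and the filter on all 12 arrays (adjusted p = 0.0867).

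The other lists did not pass camera's test in WT cells, though single members changed. TGF-beta and BMP targets split, with 6 of 20 higher, such as ID2 by 1.79 ± 0.10, and 9 lower, such as PMEPA1 by -1.88 ± 0.10 (adjusted p = 0.167). MAPK phosphatases and feedback regulators fell in 8 of 15 cases, including DUSP5 by 1.56, and rose in 2 (adjusted p = 0.0539). Of 11 osteoblast differentiation genes 6 fell, including the decoy receptor TNFRSF11B by 2.03, and ALPL, the bone alkaline phosphatase, rose by 1.14 ± 0.15 (0.0657). Metabolic genes rose singly, such as PDK4, which limits glucose oxidation, by 6.04 ± 0.11 in glycolysis (4 higher and 2 lower of 24, 0.57, with a median of -0.02 but a mean of 0.46) and FOXO1 by 2.55 ± 0.13 in insulin and IGF signalling (7 and 3 of 19, 0.14). Counts higher and lower with their camera adjusted p were 5 and 2 of 16 for adipogenic genes (0.167), 3 and 5 of 22 for cholesterol biosynthesis (0.812, median -0.11, mean 0.05 and a test towards lower), and 4 and 6 of 23 for extracellular matrix (0.914). They were 5 and 5 of 17 for the circadian clock (0.914, with a median of -0.16, a mean of -0.01 and a test towards higher), 1 and 4 of 14 for matrix metalloproteases (0.327) and 0 of 24 for G1/S (0.612). For signalling and stress lists they were 7 and 6 of 19 for Wnt (0.731), 6 and 2 of 18 for p38 MAPK (0.353), 4 and 5 of 22 for apoptosis (0.612), 3 and 4 of 20 for p53 (0.556) and 2 and 7 of 19 for interferon (0.288). They were 3 and 2 of 18 for the unfolded protein response (0.288), 1 and 6 of 18 for heat shock (0.0796), 3 and 3 of 20 for GR chaperones (0.796), 1 and 2 of 7 for 14-3-3 (0.384) and 4 and 4 of 13 for sodium transport (0.932). No ribosomal protein of 22 changed (0.617), 1 mitochondrial gene of 21 fell (0.941), and markers were 2 and 4 of 14 for epithelial (0.756), 1 and 1 of 12 for haematopoietic (0.914) and 2 and 1 of 5 for liver cells (0.3).

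The second comparison asked the same of cells with the S134A receptor. The largest rises were of the same kind: FAM90A1 by 10.81 ± 0.11, SAG at least 477-fold, KDF1 at least 443-fold, ATP4A at least 218-fold and CST9L at least 138-fold. The globin gene HBM rose by 9.35 ± 0.24, the potassium channel gene KCNA5 at least 192-fold, PCBP3, which encodes an RNA-binding protein, at least 87.1-fold and CHRDL2, a chordin-like protein, at least 86.3-fold. ACTL8 rose by 8.77 ± 0.13, with 1 of 3 vehicle arrays above background. Falls were deep as well. HAS2, which makes hyaluronan, fell at least 9.33-fold, CSF2 at least 10.8-fold, DRD1 at least 10.4-fold, CXCL8, the neutrophil chemokine, at least 9.3-fold and CCR1 at least 5.38-fold. The chemokine CX3CL1 fell by 4.68, the phosphodiesterase PDE4B by 4.31 (1 of 3 Dex arrays above background), the blood cell factor NFE2 by 4.22 and RNF43, which restrains Wnt receptors, by 4.12.

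Of the genes reported whatever they did, TSC22D3 rose by 3.94 ± 0.13, LAD1 by 3.77 ± 0.08, SGK1 by 3.27 ± 0.10, PER1 by 2.12 ± 0.09, ZBTB16 by 2.05 ± 0.12, FKBP5 by 2.01 ± 0.08 and DUSP1 by 1.34 ± 0.11 in S134A cells. IGFBP1 rose at least 32.5-fold. MT2A rose by 0.40 ± 0.12 (limma, adjusted p = 0.0183), a call that ended in 6 alternatives (without S134A vehicle 3 or S134A Dex 3 among them, with adjusted p-values up to 0.614). KLF9 changed by -0.03 ± 0.14 (0.883) and YWHAZ by -0.20 ± 0.10 (0.127). In all, 11772 genes (50.8%) changed in limma's test, 6598 higher and 5174 lower, with 908 higher and 274 lower at least 4-fold. The share that was higher fell from 56.0% to 44.7% with median scaling, which moved the median change of all genes from 0.08 to -0.01. Vehicle and Dex arrays of S134A cells shared only slide 3, and 8638 genes were called with slide as a block.

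Most inflammatory genes fell in S134A cells: 12 of 17 fell, among them CCL2 by 3.76 and LIF by 3.39, and 4 rose, also adjusted over the list alone (camera, adjusted p = 0.00268, adjusted p = 0.0754 with an estimated correlation). NOS2 rose by 3.81 ± 0.10, and the adhesion receptor ICAM1, the cytokine TNF and TNFAIP3 were the other risers. TGF-beta and BMP targets fell in 12 of 20 cases, including ID3 by 2.48, PMEPA1 by 3.38 and the inhibitory SMAD6 by 2.24, and 5 rose, including ID2 by 3.38 ± 0.10, also adjusted over the list alone (adjusted p = 0.00841, adjusted p = 0.124 with an estimated correlation). Of 14 matrix metalloproteases and plasminogen genes 10 fell, with PLAU, the urokinase, lower by 2.91, and 2 rose (adjusted p = 0.0085, adjusted p = 0.125 with an estimated correlation). AP-1 and immediate early genes fell in 11 of 18 cases, such as MYC by 2.04, and rose in 4, or 5 adjusted over the list alone: NR4A1, FOS, FOSB and the stress factor ATF3 among them (adjusted p = 0.0085, adjusted p = 0.125 with an estimated correlation). MAPK phosphatases fell in 9 of 15 cases, such as DUSP5 by 2.30, and rose in 4, such as DUSP1 (adjusted p = 0.0085, adjusted p = 0.125 with an estimated correlation). Osteoblast genes fell in 7 of 11 cases, or 8 adjusted over the list alone, with the bone transcription factor RUNX2 lower by 1.49 and BMP4 by 1.80, and 2 rose (adjusted p = 0.0085, adjusted p = 0.124 with an estimated correlation). G2/M genes fell in 10 of 24 cases, such as TOP2A, a topoisomerase of dividing cells, by 0.90, while the kinetochore motor CENPE and the mitotic activator CDC20 rose (adjusted p = 0.00906, adjusted p = 0.375 with an estimated correlation).

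Lists that rose in S134A cells were led by classical GR-induced genes, with 14 of 19 higher, also adjusted over the list alone (camera, adjusted p = 6.72e-05, adjusted p = 0.0754 with an estimated correlation). CEBPD rose by 4.67 ± 0.09 and TIPARP by 4.60 ± 0.10, while ERRFI1, a brake on EGF receptor signalling, and ANGPTL4, an inhibitor of lipoprotein lipase, fell. Of 10 metallothioneins 9 rose, among them MT1M by 1.20 ± 0.17 (adjusted p = 0.0085, adjusted p = 0.48 with an estimated correlation). Endothelial markers rose in 4 of 7 cases, such as VWF by 2.56 ± 0.09 (adjusted p = 0.0086, adjusted p = 0.333 with an estimated correlation and 0.0732 over genes above background on all 12 arrays). Ribosomal proteins rose slightly in 16 of 22 cases, or 19 adjusted over the list alone, such as RPL8 by 0.46 ± 0.12 (adjusted p = 0.0085, adjusted p = 0.599 with an estimated correlation). That shift was 0.02 after quantile normalization (adjusted p = 0.707), 0.25 with slide as a block (adjusted p = 0.0564) and 0.16 on slide 3. The list fell with array brightness within groups, which is partly built in, since brightness is the percentile subtracted from each array. With brightness as a covariate the rise was 0.11 ± 0.03.

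Lists without a camera call in S134A cells again held large single changes. IRS1, an adaptor of the insulin receptor, fell by 2.89 among insulin and IGF genes (10 higher and 8 lower of 19, adjusted p = 0.944), and the clock repressor BHLHE41 fell by 3.14 (circadian, 5 and 7 of 17, 0.363). The Wnt feedback gene NKD1 rose by 4.55 ± 0.13 (Wnt, 6 and 8 of 19, 0.776), HSPA1A, an inducible chaperone, fell by 1.82 (heat shock, 2 and 5 of 18, 0.138) and the apoptosis activator BMF by 2.98 (apoptosis, 5 and 8 of 22, 0.302). Adipogenic genes rose in 5 and fell in 7 of 16 cases (0.4, median -0.21, mean 0.17), glycolysis in 10 and 3 of 24 (0.173), cholesterol in 6 and 9 of 22 (0.355, median -0.16, mean 0.01) and extracellular matrix in 3 and 9 of 23 (0.144). The remaining counts were 5 and 1 of 24 for G1/S (0.776), 4 and 8 of 20 for p53 (0.346), 4 and 10 of 19 for interferon (0.0989), 6 and 2 of 18 for the unfolded protein response (0.4) and 3 and 3 of 20 for GR chaperones (0.338). They were 0 and 3 of 7 for 14-3-3 (0.268), 7 and 5 of 18 for p38 MAPK (0.879), 5 and 4 of 13 for sodium transport (0.878) and 10 and 0 of 21 for mitochondrial genes (0.0842). Markers were 3 and 5 of 14 for epithelial (0.4), 4 and 1 of 12 for haematopoietic (0.346) and 2 and 1 of 5 for liver cells (0.312).

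**Figure D2:**
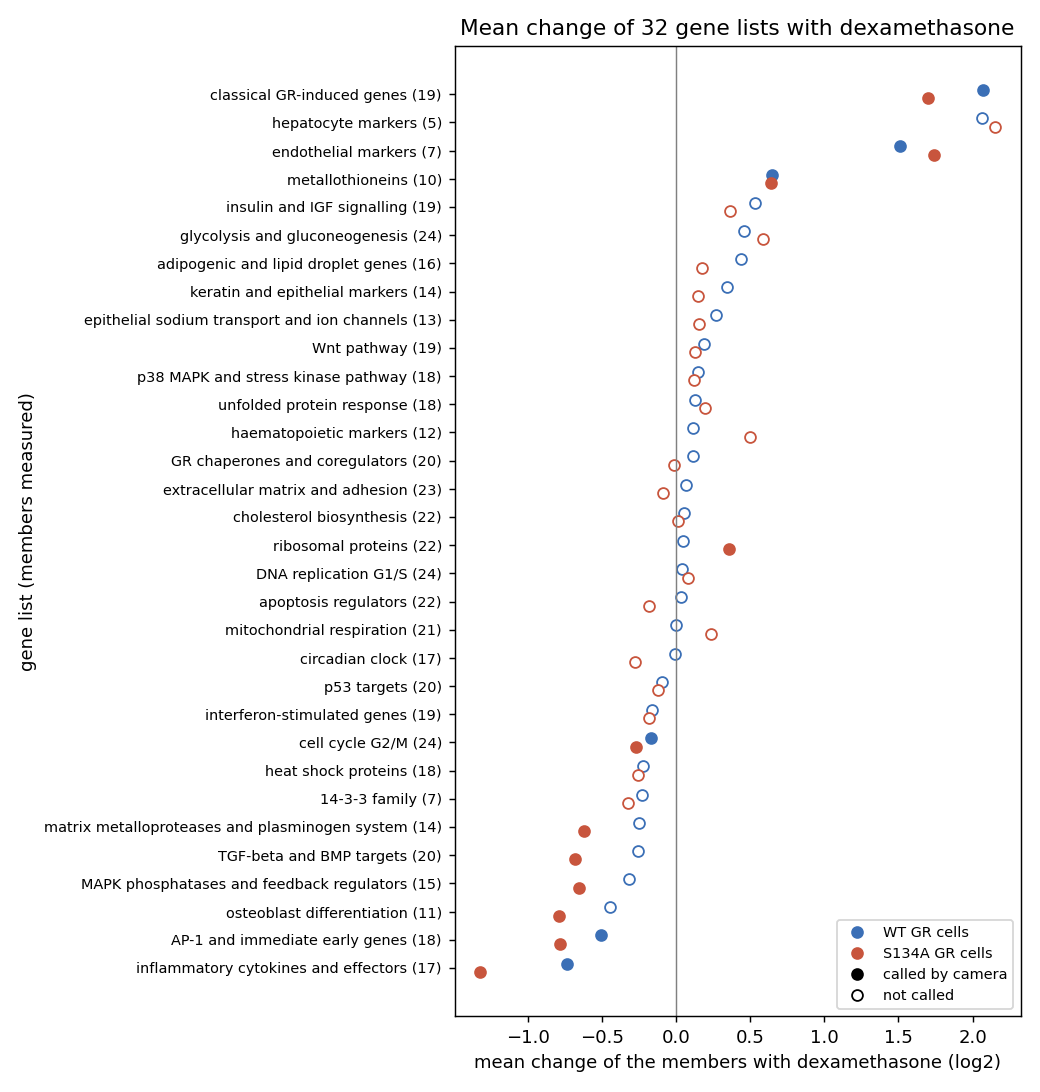
Mean log2 change of the members of each of the 32 lists with Dex in WT cells and in S134A cells, with the number of members measured. Filled points passed camera's test at the preset correlation, and the inflammatory list lay at -0.74 in WT cells and -1.32 in S134A cells.

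The third comparison asked where the hormone response differed between the populations, as the S134A change minus the WT change on the log2 scale. It cannot separate the receptor from other differences between the populations. Most genes moved the same way in both populations and further in S134A cells. CADPS, which primes secretory vesicles, rose by 4.38 in WT and 8.36 in S134A cells, a difference of 3.98 ± 0.20 (limma, adjusted p = 8.95e-06). The collectin COLEC11 rose 2.66 ± 0.16 more, NCF1, a subunit of the phagocyte oxidase, 2.98 ± 0.40 more, the inhibitory immune receptor LAIR1 3.08 ± 0.42 more and its relative LILRA6 2.63 ± 0.41 more. RUNX3, a transcription factor of blood cells (3.41 ± 0.40), the coagulation factor F11 (2.72 ± 0.40) and PRAMEF2, of a family with near-identical copies (2.57 ± 0.31), differed upwards too. Each had a group not well above background, so that these sizes are uncertain. TLR4, the receptor for bacterial endotoxin, changed by -0.63 in WT and -3.48 in S134A cells, a difference of -2.85 ± 0.09 (adjusted p = 1.85e-07). CX3CL1 differed by -2.70 ± 0.26, RNF43 by -2.56 ± 0.22 and NXPH2, a neurexin ligand, by -2.72 ± 0.47. HAS2 (-3.49 ± 0.22), the intestinal factor ISX (-3.27 ± 0.40) and EDN3, an endothelin (-2.48 ± 0.46), differed downwards with a group not well above background. The phosphatase DUSP23 rose by 3.01 in WT cells and changed by 0.03 in S134A cells, a difference of -2.98 ± 0.31. LEFTY1, an inhibitor of nodal signalling, rose in WT and fell in S134A cells, a difference of -2.68 ± 0.26. CELSR1 (2.88 ± 0.72), SERPINB7 (2.84 ± 0.79) and TCIM (-2.43 ± 0.49) completed the named set, but the calls of CELSR1 and SERPINB7 each ended in 14 alternatives and that of TCIM with normexp on the negative controls.

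KLF9, ZBTB16 and FKBP5 did not follow the larger S134A response. KLF9 rose in WT cells and not in S134A cells, a difference of -0.98 ± 0.19 (limma, adjusted p = 0.0112), ZBTB16 rose less in S134A cells by -0.99 ± 0.16 (0.00459) and FKBP5 by -0.45 ± 0.11 (0.0261). This last call ended with slide as a block and in 6 other alternatives (without WT vehicle 3, WT Dex 1, WT Dex 3, S134A vehicle 1 or S134A Dex 3 among them, with adjusted p-values up to 0.117). IGFBP1 rose more in S134A cells, by 2.11 ± 0.21 (0.000252), with S134A vehicle not well above background. Under Dex the populations differed by only 0.43, so most of the 2.11 rests on dim vehicle levels. Its size and p-value are therefore uncertain. The difference was 0.35 ± 0.14 for SGK1, -0.28 ± 0.13 for PER1, -0.31 ± 0.15 for DUSP1, -0.17 ± 0.11 for LAD1, -0.04 ± 0.18 for TSC22D3, 0.11 ± 0.17 for MT2A, 0.00 ± 0.15 for YWHAZ and -0.32 ± 0.12 for NR3C1 (adjusted p = 0.124), none past the threshold. The second NR3C1 probe differed by -0.53 ± 0.12 (adjusted p = 0.0227).

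The responses were related but unequal. Of the calls, 3063 genes were higher and 2677 lower with Dex in both populations, where 963 and 730 would overlap if the calls were independent. The comparisons shared no arrays but shared each gene's variance in the single fit, so their calls are not fully independent. The slope of the S134A on the WT response over the 12628 genes called in either was 1.35, 1.32 on slide 3 alone and 1.33 with slide as a block, against 0.927 to 1.06 between slides within WT cells. Over the genes called in WT cells the slope was 1.27. The test of the difference called 2182 genes (9.42%), 1111 higher and 1071 lower, and the response was larger in S134A cells for 2024 of them and in WT cells for 158. With slide as a block it called 1076 genes, of which 1021 were called in the same direction without it. The higher genes were 50.9% of the calls, but 42.8% with slide as a block and 66.2% without WT vehicle 1. Of the 2182 genes, 55 were called in opposite directions in the 2 populations. The count ranged from 1307 without S134A vehicle 1 and 1396 without WT vehicle 3 to 4543 without WT vehicle 1.

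**Figure D3:**
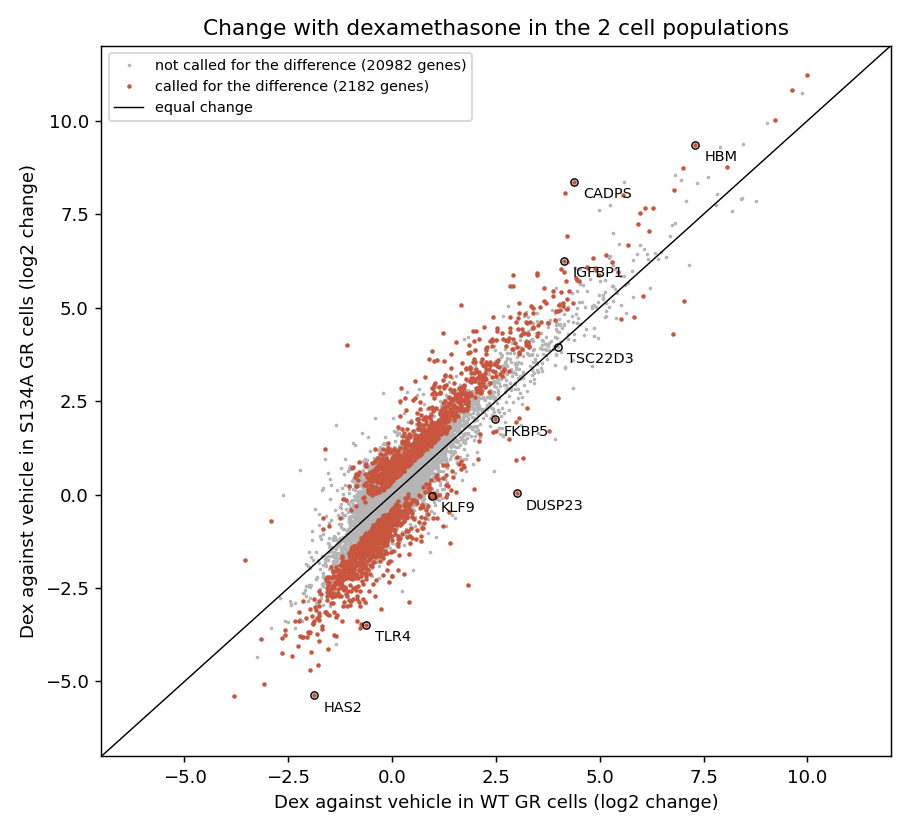
Log2 change with Dex in S134A cells against that in WT cells for each of 23164 genes, with the 2182 genes called for the difference in red and the line of equal change. Most red points lie further from 0 in S134A cells than in WT cells.

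Of the lists, 14 differed between the responses at camera's preset correlation and none with an estimated correlation. The fry test called 12 of these and also glycolysis and haematopoietic markers, but not extracellular matrix (adjusted p = 0.106) or ribosomal proteins (adjusted p = 0.165). Here and in the next paragraph, lower and higher describe the S134A response minus the WT response, not the level in the cells. TGF-beta and BMP targets had a lower response in S134A cells in 8 of 20 cases, or 9 adjusted over the list alone (camera, adjusted p = 0.000169, adjusted p = 0.0766 with an estimated correlation). Among the lower were ID3 (-1.61 ± 0.09), PMEPA1 (-1.50 ± 0.14) and the receptor TGFBR2 (-1.06 ± 0.11), while ID2 was higher (1.59 ± 0.14). Inflammatory genes were lower in 7 of 17 cases, such as PTGS2 by -1.50 ± 0.11 and CCL2 by -1.18 ± 0.14, or 9 adjusted over the list alone, and the cytokine IL6 and NOS2 were higher (adjusted p = 0.00426, adjusted p = 0.0766 with an estimated correlation). MAPK phosphatases and feedback regulators were lower in 5 of 15 cases, or 8 adjusted over the list alone, such as DUSP16 by -0.46 ± 0.10, and DUSP8 was higher (adjusted p = 0.00469, adjusted p = 0.0909 with an estimated correlation). Circadian genes were lower in 3 of 17 cases, including BHLHE40 by -1.29 ± 0.21 and BHLHE41 by -1.52 ± 0.25 (adjusted p = 0.00785, adjusted p = 0.0885 with an estimated correlation). Matrix metalloproteases and plasminogen genes were lower in 4 of 14 cases, or 5 adjusted over the list alone, such as PLAU by -1.45 ± 0.10, and PLAUR, the urokinase receptor, was higher in a call that 8 alternatives ended (adjusted p = 0.0134, adjusted p = 0.138 with an estimated correlation). Osteoblast genes were lower in 3 of 11 cases, such as BMP4 by -1.10 ± 0.17 (adjusted p = 0.0134, adjusted p = 0.0909 with an estimated correlation). Within slide 3 the mean difference was -0.38 for TGF-beta targets, -0.79 for inflammatory genes and -0.47 for MAPK phosphatases.

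Classical GR-induced genes had a lower change in S134A than in WT cells in 7 of 19 cases, also adjusted over the list alone, such as the apoptosis inhibitor BIRC3 by -1.09 ± 0.19, and CEBPD a higher one by 0.75 ± 0.13 (camera, adjusted p = 0.0191, adjusted p = 0.175 with an estimated correlation). Among the 7, ANGPTL4 and ERRFI1 fell in S134A cells. The list call ended without WT Dex 3 (adjusted p = 0.0531) and over genes above background on all 12 arrays (0.0801). AP-1 genes were lower in 5 of 18 cases, or 7 adjusted over the list alone, such as JUNB by -1.31 ± 0.28, with ATF3 higher (adjusted p = 0.0191, adjusted p = 0.171 with an estimated correlation and 0.0531 without WT Dex 3). Apoptosis regulators were lower in 6 of 22 cases, such as BMF by -2.20 ± 0.24 and the survival gene BCL2L1 by -1.42 ± 0.22, with a median of 0.02 but a mean of -0.22 (adjusted p = 0.0289, adjusted p = 0.313 with an estimated correlation and 0.057 without WT Dex 3). Insulin and IGF genes were lower in 3 of 19 cases, or 6 adjusted over the list alone, with IRS1 lower by -2.10 ± 0.16 and the mTOR inhibitor DDIT4 by -1.71 ± 0.15 (adjusted p = 0.0439, adjusted p = 0.138 with an estimated correlation). Adipogenic genes were lower in 4 of 16 cases, such as G0S2, an inhibitor of lipolysis, by -1.54 ± 0.14 and CEBPB by -1.29 ± 0.12, and higher in 2 (adjusted p = 0.0394, adjusted p = 0.138 with an estimated correlation). The insulin and adipogenic calls each ended in 9 further alternatives, with slide as a block at an adjusted p of 0.0691 and 0.0765. Both ended without WT Dex 1, WT Dex 3, WT vehicle 2 or WT vehicle 3 (adjusted p-values of 0.0531 to 0.0673), and the insulin call without WT vehicle 1 (0.0798) or S134A Dex 1 (0.0564). Extracellular matrix genes were lower and higher in 1 of 23 cases each, with THBS2, a matrix thrombospondin, higher by 1.60 ± 0.28 (adjusted p = 0.0191, adjusted p = 0.354 with an estimated correlation, 0.111 with slide as a block and 0.0589 without WT vehicle 2). Ribosomal proteins had a mean difference of 0.31 with none of 22 called (adjusted p = 0.00475, adjusted p = 0.611 with an estimated correlation and 0.431 after quantile normalization). Mitochondrial genes had a mean difference of 0.24 with 1 of 21 called, or 3 adjusted over the list alone (adjusted p = 0.0151, adjusted p = 0.463 with an estimated correlation, 0.107 after quantile normalization and 0.0676 with slide as a block).

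The fourth comparison asked how the populations differed without hormone. Germ cell and cancer-testis genes stood out: GAGE1 was at least 8.62-fold lower in S134A cells, CTAG1A lower by -3.64 ± 0.13 and CTAG2 by -3.42 ± 0.22. VCX2 was higher by 2.59 ± 0.11 and VCX by 2.58 ± 0.13. The homeobox gene RHOXF2 was called higher too, but its probe was above background on no WT vehicle array and no size is given. Several of these have near-identical copies that the probes may not separate. HIF3A, of the hypoxia-inducible factors, was higher by 3.59 ± 0.15 (limma, adjusted p = 4.46e-07), the microfibril gene MFAP4 by 3.31 ± 0.16, the endothelial proteoglycan ESM1 by 2.96 ± 0.34 and TF by 2.46 ± 0.16, with 2 of 3 WT arrays above background. RARRES2, which encodes chemerin, was higher by 2.41 ± 0.22 and the pseudogene PCDHB17P by 3.25 ± 0.43 (1 of 3 WT arrays each), and GIMAP5 at least 1.8-fold. The pluripotency gene DPPA2 was at least 3.76-fold, NXNL2 at least 4.76-fold, the small heat shock gene HSPB7 at least 3.76-fold and RUNX3 at least 2.66-fold lower. TCL1A, an AKT coactivator of lymphocytes, was lower by -4.01 ± 0.34, the dehydrogenase DHRS2 by -2.94 ± 0.09 and SYTL1, a vesicle protein, by -2.69 ± 0.10. The calls of NXNL2 and HSPB7 ended with normexp on the negative controls, and that of HSPB7 also in a fit of only the arrays compared.

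Interferon-stimulated genes were higher in S134A vehicle in 9 of 19 cases, or 11 adjusted over the list alone, with BST2, which tethers virions, higher by 1.64 ± 0.10 and MX2 by 1.16 ± 0.11, while IFI44L was lower (camera, adjusted p = 0.000196, adjusted p = 0.236 with an estimated correlation). This was the only list of 32 that camera called under vehicle, and its mean was 0.39 on slide 1 and 0.51 on slide 3. In lists without a call, ICAM1 was lower by -1.76 ± 0.09 (2 of 3 S134A arrays above background) and the cytokine IL1B higher by 1.31 ± 0.14. The proteases MMP10 and MMP1 differed by 2.24 ± 0.12 and -1.07 ± 0.12. Among the genes reported whatever they did, DUSP1 (-0.47 ± 0.11), SGK1 (-0.34 ± 0.10), PER1 (0.31 ± 0.09) and LAD1 (0.28 ± 0.08) differed, in calls that 4, 12, 15 and 12 alternatives ended. IGFBP1 was at least 1.36-fold lower, with 1 of 3 WT arrays above background, in a call that ended with normexp on the negative controls. The differences of KLF9 (0.35 ± 0.14), ZBTB16 (0.20 ± 0.12), FKBP5 (0.03 ± 0.08), TSC22D3 (0.06 ± 0.13), MT2A (0.08 ± 0.12) and YWHAZ (-0.08 ± 0.10) did not pass the threshold. In total 4017 genes (17.3%) differed in limma's test, 2185 higher and 1832 lower, of which 440 by at least 2-fold. With slide as a block the count was 3669. The count was 2305 without WT vehicle 3, 2081 without S134A vehicle 1 and 2331 without S134A vehicle 2.

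The fifth comparison asked how the populations differed in the presence of Dex. CADPS was higher in S134A cells by 3.41 ± 0.14, NCF1 by 3.11 ± 0.29 and THBS2 by 2.96 ± 0.20. GIMAP5 was at least 2.23-fold higher, and GAGE1 at least 6.13-fold, NXNL2 at least 6.91-fold and DPPA2 at least 3.9-fold lower. CTAG1A was lower by -3.66 ± 0.13 and CTAG2 by -4.12 ± 0.22 (2 of 3 S134A arrays above background). NR3C1 was lower by -0.40 ± 0.09 (limma, adjusted p = 0.00532), a call that ended with array brightness as a covariate. Also lower were ZBTB16 by -0.80 ± 0.12, DUSP1 by -0.77 ± 0.11, KLF9 by -0.62 ± 0.14 and FKBP5 by -0.43 ± 0.08. IGFBP1 was higher by 0.43 ± 0.15, a call that ended in 11 alternatives. The differences of LAD1 (0.11 ± 0.08), PER1 (0.03 ± 0.09), SGK1 (0.02 ± 0.10), TSC22D3 (0.01 ± 0.13), MT2A (0.19 ± 0.12) and YWHAZ (-0.08 ± 0.10) did not pass the threshold. In limma's test 8462 genes (36.5%) differed, 5322 higher and 3140 lower, and 6373 were called with slide as a block. The higher genes were 62.9% of the calls, but 55.2% after quantile normalization and 48.3% with array brightness as a covariate. At least 2-fold, 497 were higher and 505 lower.

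Camera called 13 of 32 lists under Dex, and TGF-beta and BMP targets and inflammatory genes also held with an estimated correlation. TGF-beta and BMP targets were lower in 13 and higher in 4 of 20 cases, with ID3 lower by -1.85 ± 0.07 and TGFBR2 by -1.24 ± 0.08, also adjusted over the list alone (camera, adjusted p = 2.07e-05, adjusted p = 0.0413 with an estimated correlation). Inflammatory genes were lower in 9 and higher in 3 of 17 cases, with CCL2 lower by -1.99 ± 0.10, ICAM1 by -1.36 ± 0.09 and PTGS2 by -0.97 ± 0.07 (adjusted p = 0.000759, adjusted p = 0.0413 with an estimated correlation). The mean of these lists was -0.58 and -0.57, and -0.59 and -0.79, on slides 2 and 3. The inflammatory call ended over genes above background on all 12 arrays (adjusted p = 0.0617). MAPK phosphatases were lower in 9 and higher in 2 of 15 cases, such as DUSP14 by -0.95 ± 0.14 (adjusted p = 0.00239, adjusted p = 0.0925 with an estimated correlation). Extracellular matrix genes were lower in 8 and higher in 2 of 23, such as the collagen COL3A1 by -1.14 ± 0.16 (adjusted p = 0.00339, adjusted p = 0.208 with an estimated correlation). G2/M genes were lower in 8 of 24, or 6 adjusted over the list alone, such as TOP2A by -0.92 ± 0.11 (adjusted p = 0.00303, adjusted p = 0.208 with an estimated correlation). Classical GR-induced genes were lower in 9 and higher in 2 of 19 (adjusted p = 0.0109, adjusted p = 0.142 with an estimated correlation). GR chaperones and coregulators were lower in 6 and higher in 1 of 20, such as NR3C2, the mineralocorticoid receptor, by -1.11 ± 0.10 (adjusted p = 0.015, adjusted p = 0.142 with an estimated correlation).

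Adipogenic genes were lower in 8 and higher in 3 of 16, such as CEBPB by -1.25 ± 0.09 (camera, adjusted p = 0.0109, adjusted p = 0.0925 with an estimated correlation, and 0.065 over genes above background on all 12 arrays). Insulin and IGF genes were lower in 7 and higher in 4 of 19, such as IRS1 by -1.91 ± 0.11 (adjusted p = 0.0337, adjusted p = 0.142 with an estimated correlation, 0.0528 after quantile normalization and 0.052 with the mean over a gene's probes). Circadian genes were lower in 5 and higher in 2 of 17, such as BHLHE41 by -1.81 ± 0.17 (adjusted p = 0.0337, adjusted p = 0.142 with an estimated correlation, 0.0548 without S134A Dex 1 and 0.0863 without WT Dex 3). Quantile normalization ended the circadian call too (camera, adjusted p = 0.0641). Interferon-stimulated genes were higher in 7 and lower in 1 of 19, such as MX2 by 1.78 ± 0.11 and ISG15 by 0.77 ± 0.09 (adjusted p = 0.0337, adjusted p = 0.233 with an estimated correlation). Without S134A Dex 1 or 3, WT Dex 2 or WT vehicle 1 the interferon call ended, with adjusted p-values of 0.0515 to 0.0878. Ribosomal proteins were higher in 17 of 22 cases, or 19 adjusted over the list alone, with a mean of 0.35 (adjusted p = 0.00274, adjusted p = 0.567 with an estimated correlation). The mean was -0.01 after quantile normalization and 0.05 ± 0.04 with array brightness as a covariate. Mitochondrial genes were higher in 7 of 21 (adjusted p = 0.0337, adjusted p = 0.547 with an estimated correlation and 0.344 after quantile normalization). The mitochondrial call also ended with normexp on the negative controls (0.11), with slide as a block (0.0636), without S134A Dex 1 (0.0605) and without WT Dex 3 (0.0535). The S134A Dex arrays were the dimmest of the 12, with 75th percentiles of 1749, 1779 and 1445.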

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

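The array brightness covariate, slide 3 alone and the counts over other splits of the arrays were chosen after the results were seen, and so was the use as tests of quantile normalization, slide as a block and the receptor level, which were planned as values.

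The 2182 genes whose response to dexamethasone differed between S134A and WT cells in limma's test stand out, and among the genes named here these are given as S134A minus WT response (log2). The difference was above 0 for CADPS (3.98), RUNX3 (3.41), LAIR1 (3.08), NCF1 (2.98), CELSR1 (2.88), SERPINB7 (2.84), F11 (2.72) and COLEC11 (2.66). It was also above 0 for LILRA6 (2.63), PRAMEF2 (2.57), HBZ (2.46), GRIP2 (2.21), IGFBP1 (2.11), HBM (2.05), THBS2 (1.60) and ID2 (1.59). Smaller such differences were those of HBA2 (1.46), ZAP70 (1.34), FAM90A1 (1.19), CPNE7 (1.09), NKD1 (1.04), VWF (0.91), DUSP8 (0.87) and NOS2 (0.76). The smallest of these were CEBPD (0.75), ISG15 (0.72), ACTL8 (0.70), IL6 (0.65), MX2 (0.63), ATF3 (0.62), PAGE1 (0.55) and PLAUR (0.39). The difference was below 0 for HAS2 (-3.49), ISX (-3.27), DUSP23 (-2.98), TLR4 (-2.85), NXPH2 (-2.72), CX3CL1 (-2.70), LEFTY1 (-2.68) and RNF43 (-2.56). Next came EDN3 (-2.48), TCIM (-2.43), NFE2 (-2.28), BMF (-2.20), CXCL8 (-2.13), IRS1 (-2.10), NPTX2 (-2.06) and CSF2 (-1.98). They were followed by PDE4B (-1.90), DDIT4 (-1.71), IL6R (-1.63), ID3 (-1.61), ANGPTL4 (-1.60), DRD1 (-1.59), IL1B (-1.55) and G0S2 (-1.54). Smaller decreases relative to WT were those of ADRA1B (-1.53), BHLHE41 (-1.52), PMEPA1 (-1.50), PTGS2 (-1.50), MFAP4 (-1.47), PLAU (-1.45), SMAD6 (-1.43) and BCL2L1 (-1.42). Below these in size came JUNB (-1.31), HIF3A (-1.30), CEBPB (-1.29), BHLHE40 (-1.29), RUNX2 (-1.23), CCL2 (-1.18), LIF (-1.14) and BMP4 (-1.10). Responses nearer to those in WT cells were those of BIRC3 (-1.09), TGFBR2 (-1.06), MYC (-1.05), IER3 (-1.04), NR3C2 (-1.03), IER2 (-1.01), ERRFI1 (-1.002) and ZBTB16 (-0.99). Nearer still were KLF9 (-0.98), HSPA1A (-0.88), MMP10 (-0.87), DUSP5 (-0.74), PDK4 (-0.71), AMIGO2 (-0.70), TOP2A (-0.59) and CDC25C (-0.49). The smallest were DUSP16 (-0.46) and FKBP5 (-0.45). Some of these calls ended in alternatives: MX2 in 13, TOP2A, CELSR1 and SERPINB7 in 14 each, PLAUR in 8, FKBP5 in 7 and CDC25C in 6. Slide as a block ended those of RUNX2, PDK4 and ERRFI1. As means over their probes MYC (-0.27) and LIF (-0.48) were no longer called, nor were ANGPTL4 (-0.40) and TCIM (-0.42) with normexp on the negative controls. For genes outside the planned rule for this comparison no alternative was run. The size is uncertain where no array of a group was well above background on the probe tested, as for ANGPTL4, CELSR1, CSF2, CXCL8, DRD1, EDN3, F11, GRIP2, HAS2, IGFBP1, IL1B, ISX, PRAMEF2, RUNX3, SERPINB7, TCIM and ZAP70.

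As lists, the mean difference was -0.58 for inflammatory genes, -0.42 for TGF-beta and BMP targets, -0.37 for classical GR-induced genes, -0.37 for matrix metalloproteases, -0.34 for osteoblast genes and -0.34 for MAPK phosphatases. It was -0.28 for AP-1 genes, -0.27 for the circadian clock, -0.26 for adipogenic genes, -0.22 for apoptosis regulators, -0.17 for insulin and IGF genes and -0.15 for extracellular matrix. The mean was 0.24 for mitochondrial respiration and 0.31 for ribosomal proteins. None of these 14 list calls held with an estimated correlation. Over genes above background on all 12 arrays the means were -0.09 for adipogenic and -0.18 for classical GR-induced genes, and after quantile normalization 0.11 for mitochondrial respiration and 0.05 for ribosomal proteins, none of them called.

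Dexamethasone moved genes further in S134A than in WT cells, with a slope of 1.35 and a jackknife standard error of 0.0397. The slope was 1.34 after quantile normalization, which argues against the scaling between arrays as the cause. It was 1.33 with slide as a block and 1.32 on slide 3, above each slope between slides in WT cells, which argues against the slide. The amount of receptor stays open: NR3C1 differed by -0.082 (log2) under vehicle on the probe tested and by 0.24 ± 0.09 on the other, but no probe is known to detect the transfected receptor, so that this cannot be told apart from the S134A change itself. A difference between the selected populations other than the mutation may also be the cause and was not tested.

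Ribosomal proteins were higher in S134A than in WT cells under dexamethasone, by 0.35 ± 0.12 (mean log2 ± SE). Within groups the list's mean level fell with array brightness over the 12 arrays (r = -0.976, rho = -0.944, each with an exact within-group permutation p of 0.00231). Without the 2 arrays farthest in brightness r was -0.955, and of the 2 lists tested the other, mitochondrial respiration, gave r = -0.865 and rho = -0.846 (permutation p = 0.00231 and 0.00849, r = -0.727 without the 2 farthest arrays, adjusted p of r 0.00231 for both lists). Brightness here is the log2 of the array percentile that was subtracted from every level. A negative correlation is therefore partly built in for any list whose signal does not scale fully with that percentile. These r and rho values and their permutation p-values thus cannot decide about the cause. With brightness as a covariate the ribosomal difference under dexamethasone was 0.055 ± 0.04, and after quantile normalization -0.0103. That difference thus depended on how arrays were scaled, and array brightness or scaling stays a candidate cause. No biological explanation was tested. With the covariate the ribosomal list still differed between the responses (0.15 ± 0.04) and rose with dexamethasone in S134A cells (0.11 ± 0.03). The mitochondrial list also differed between the responses (0.16 ± 0.05). After quantile normalization these shifts were 0.05, 0.02 and 0.11 and no longer called. The covariate comes from the scaling percentile itself, so this fit does not separate brightness from scaling. Both stay open for these shifts.

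For the count of 2182 genes, 3 of 100 regroupings of the receptor labels within treatment, the real one included, gave as many, a share under 0.05, and the highest other count was 4077. A regrouping that mixes the populations within a treatment puts their difference into the spread, which lowers its count. That share therefore does not measure how often chance alone gives as many genes. The regroupings with more genes relabelled 4 of 6 vehicle arrays and no Dex arrays, which by construction puts the difference between the populations into the comparison. Why they gave more genes was not tested. The other comparisons allow 10 splits, too few for a share under 0.05, and in each only the real split, 1 of the 10, gave as many genes. Every other split mixes the groups compared, so their difference enters the spread and very few calls follow by construction. These counts cannot decide about chance. The real count and the highest other were 6651 and 1 for dexamethasone in WT cells, 11772 and 0 in S134A cells, 4017 and 1 between populations under vehicle and 8462 and 1 under dexamethasone.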

How the results depend on the processing

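The normexp fit on negative controls, array brightness as a covariate, slide 3 alone and the filter on all 12 arrays with a 2-fold change were chosen after seeing the data. Of 610 called results for named genes, 470 kept their call in every alternative run, and of 45 called lists 25 kept theirs except with an estimated correlation. A gene that the filter on all 12 arrays removed could not lose its call there and was judged on the other alternatives only. With that filter 625 named results, called or not, stayed the same and 4 became stronger, against 740 that stayed the same with the series matrix values. List tests were not run with slide as a random block, trend and robust variance, array weights, fits of only the arrays compared or the brightness covariate, and named genes and lists were not run with limma's default normexp.

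Counts are given for dexamethasone in WT cells, in S134A cells, the interaction, and S134A against WT under vehicle and under dexamethasone. With default normexp they were 790, 2857, 1, 47 and 325. That fit failed on WT vehicle 1 and S134A Dex 2, whose fitted background means were -1349 and -1018, and which held 4 and 6 spots with a local background far above the signal. With normexp on the negative controls they were 6042, 11591, 1609, 3877 and 8745. With array weights, whose fit stopped before it converged, they were 4456, 17474, 2969, 2943 and 12440. Requiring a 2-fold change left 1850, 3302, 637, 440 and 1002, and doing so among genes above background on all 12 arrays 1155, 2309, 414, 263 and 573, both being stricter by construction. At an adjusted p under 0.01 the last 3 counts were 808, 1774 and 4384. For the interaction, no filter gave 1454 and slide as a block 1076, for the vehicle comparison the arrays compared alone gave 1925, and for that under dexamethasone the brightness covariate gave 4618. The cause was not tested.

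Leaving out single arrays gave 5356 to 7303 and 9844 to 12809 genes for dexamethasone in WT and S134A cells, and 5702 to 9864 between populations under dexamethasone. The interaction ranged from 1307 (without S134A vehicle 1), with 1396 without WT vehicle 3, to 4543 (without WT vehicle 1). The vehicle comparison ranged from 2081 (without S134A vehicle 1) to 4561, with 2305 without WT vehicle 3 and 2331 without S134A vehicle 2. The slope ranged from 1.32 to 1.37 and was 1.45 with the filter on all 12 arrays.

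Directions turned for 3 named genes and 1 list, none called in the alternative. PTPRC with dexamethasone in S134A cells was 0.052 with normexp on the negative controls against -0.76, ENO1 between populations under dexamethasone -0.0046 after quantile normalization, TRIB3 in the interaction 0.17 as the mean over its probes, and ribosomal proteins between populations under dexamethasone -0.0103 after quantile normalization. The cause was not tested.

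Replicate numbers did not pair the arrays: deviations of the 18 same-number pairs correlated at -0.324 to 0.197, 4 of them above 0.1, and 3 of 12 arrays correlated best with their own number. With the replicate number as a block the counts were 6118, 11309, 1597, 3214 and 7689, and the NR3C1 level under vehicle differed by -0.08. Signal over background limits dim genes, whose sizes are bounds or uncertain.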

Other observations

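The test of cross-hybridisation in this part was chosen after the result was seen. The other tests were written down before their result was seen, on patterns that the data had raised. The genes of the first paragraph were chosen after their values were seen.

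Many genes that were not well above background on any vehicle array were measured on every Dex array. There were 173 in WT and 339 in S134A cells, 138 of them in both, out of 287 and 368 genes dim under vehicle. Such genes passed the filter only through a group where they were bright, so these numbers are partly set by the filter. Of the 374 in either population 87.7% were called higher in both. Over all genes, 3063 were called higher in both, of 3381 higher in WT and 6598 higher in S134A cells. CSF3, a growth factor of neutrophils, rose at least 40.3-fold in WT and 78.4-fold in S134A cells, and PNLIP, the pancreatic lipase, at least 61.0-fold and 67.0-fold. A smaller set was called in opposite directions: 30 genes rose in WT and fell in S134A cells and 25 did the reverse. NPTX2, a neuronal pentraxin, changed by 1.23 ± 0.21 in WT and -0.83 ± 0.21 in S134A cells (log2 ± SE), the adrenergic receptor ADRA1B by 0.77 ± 0.10 and -0.76 ± 0.10 and the interleukin receptor IL6R by 0.74 ± 0.13 and -0.89 ± 0.13. Each of these 55 genes passed limma's test of the difference. This follows largely from how they were chosen, since called changes in opposite directions add up in the difference.

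Cancer-testis genes, which are normally used in germ cells and reactivated in tumours, differed between the populations without hormone. Of 59 measured members of a list written after the named genes were seen, 24 were called, 9 higher and 15 lower in S134A cells, and 17 of these were called in the same direction under dexamethasone. SSX1 was lower by -2.46 ± 0.34 and VCX3A higher by 2.23 ± 0.24. By limma's estimates, at least 2-fold changes were called for 23.7% of the list, against a median of 1.69% in 10000 random lists matched on signal (permutation p = 1e-04, the smallest they can give). The share counts SSX3, whose bound for a dim group is only at least 1.42-fold, and RHOXF2, for which no size is given. Without the members already named the share, which still counts SSX3, was 13.7% against 1.96%, with a permutation p of 0.00020. The members left include relatives of named genes, such as VCX3A beside VCX and VCX2, whereas random lists draw genes singly. The choice of genes is therefore not excluded as the cause. Vehicle arrays received no dexamethasone, so its action during the treatment cannot account for a difference under vehicle. Of the called members 20.8% had a called interaction, against 9.42% of all genes, but the vehicle arrays enter both tests. That share therefore cannot decide about other hormone action, which stays open. The median absolute log2 difference of the called members was 1.10 under vehicle, by which they were chosen. Their median absolute change with dexamethasone in S134A cells was 0.32. Cross-hybridisation also stays open, since only 1 family (PAGE1 lower, PAGE4 higher) went both ways. A candidate explanation is that the separately selected populations differ in which germ cell genes are silenced, a hypothesis that these arrays did not test.

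Genes induced at least 4-fold by dexamethasone in WT cells followed each other in the order of tested genes more often than random placement gave. Neighbours were successive tested genes of a chromosome by start position in the RefSeq table. Untested genes between them were skipped and no limit was set on the distance. Among 454 such genes of the 14860 placed, 37 neighbouring pairs occurred against a random median of 14 (10000 placements, permutation p = 1e-04, the smallest they can give). Without pairs whose symbols share their first 3 letters there were 27 against 13 (permutation p = 0.0004, and 0.0002 with placements matched on signal). Related genes remain among the 27, such as the globins HBZ, HBM and HBA2 and the interleukins IL36G and IL1F10, so that cross-hybridisation is not excluded. Examples are EDN3 with PHACTR3 (6.77 and 5.33, log2), FKBP5 with ARMC12 (2.47 and 2.45), ZAP70 with CNGA3 (5.91 and 5.24) and CPNE7 with DPEP1 (3.38 and 5.79). Hormone action that reaches genes near each other is a candidate explanation. The distance within a pair and a transcript reading into its neighbour were not tested.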
